A study of Mus musculus with 6 samples.

How the data were processed

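Chromatin immunoprecipitation with an antibody against mSin3A, followed by sequencing (ChIP-seq), was done on CD8 T cells sorted from the spleens of wild-type (WT) mice and of mice lacking the transcription factors Tcf1 and Lef1. The series holds 6 samples: for each genotype a ChIP library in condition 1, a ChIP library in condition 2 and an input library. The labels do not say how the conditions differ, so they were not treated as replicates. Each combination of genotype and condition is therefore 1 library. No animal numbers are given, and each p-value below describes these libraries, not the genotypes.

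The authors deposited 1 list of enriched regions (islands) for each of the 4 ChIP libraries, and these were used here. The 2 input libraries were not analysed here. Reads were checked with FastQC, aligned with Bowtie2 2.2.5 and turned into islands with SICER 1.1 on the mouse build mm9, per the submitters' processing notes. SICER joins neighbouring windows of enriched signal into broad islands. Its window, gap and false discovery settings, and whether the inputs served as the background, are not given in the sources used here. In every list the island starts as deposited fell on multiples of 200 bp. Islands lay at least 800 bp apart, with the deposited end counted as part of the island. Each deposited list has 4 columns with no header: chromosome, start, end and a whole number. That number was read as the count of ChIP reads in the island, from the layout of a SICER list and from the values, since the file itself does not name it. The deposited counts are not scaled for library size or island width. Total sequencing depth is not given, so the island reads are the only measure of depth here, and intervals on counts cover counting error only. Coordinates are mm9, 1-based at the start: 1 was added to each deposited start, and ends are as deposited. Widths and called lengths in bp are the deposited end minus the deposited start.

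No island ended beyond an mm9 chromosome, whereas 346 islands over the 4 lists ended beyond the chromosomes of mm10. The gene annotation at hand is on mm10 (GRCm38), and its coordinates were not used. No gene was assigned to any island, so the 14 gene and cell type lists fixed beforehand were not tested, and regions are given by position.

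Lists were compared by the share of islands with at least 1 bp in common with the other list (Wilson 95% interval) and by the share of bases. Overlap under random placement came from 1000 uniform placements of each list within the chromosome spans covered by the 4 lists (one-sided permutation test). Islands of all 4 lists that shared a base or touched were merged into 23510 regions, and each was recorded as called or not called in each library. Genotype-specific regions were those called in both libraries of one genotype and in neither of the other. Their number was set beside the same count for the other ways of dividing the 4 libraries into pairs, which make 3 splits in all, too few for a p-value below 0.05. Whether genotype-specific calls recurred across conditions was tested with Fisher's exact test, two-sided, over regions, which are not independent replicates. The share of islands on each of 20 chromosomes was compared within a condition with Fisher's exact test and Benjamini-Hochberg adjustment. Regions to be named were fixed before the data were examined: the 10 WT-only and 10 deficient-only regions with the best read ranks, taking the worse of the 2 percentile ranks, and the 5 regions called in all 4 libraries with the best ranks. The overlaps, the 3 splits, the recurrence test and the chromosome test were fixed at that time too.

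Read ratios in regions called in all 4 libraries were added after the data were seen. They are log2 ratios of summed island reads, deficient over WT, centred on the median of each condition, which was -0.06 in condition 1 and -0.09 in condition 2. Their exact (Clopper-Pearson) 95% intervals cover counting error only. The 5 regions named in each direction are those with the largest ratio in the condition where it was smaller. The comparisons of recovery, of read density and of regions called in 3 libraries were also added, as was the comparison by called length. One further test, of whether regions called in 1 genotype are the end of a graded difference in reads, was dropped after its result was seen, because regions called in every library are limited in the ratios they can show. Alternatives were a reciprocal overlap of 50%, joining within 2 kb, the upper 50% of each list by reads, lists shortened to the length of the shortest (11151 islands), autosomes only, islands of at least 1 kb, and, added later, other scalings of the read ratios and the removal of regions above 100 reads per kb. Functions were tested on simulated data: all 2413 simulated regions of known call pattern were recovered with that pattern, and a list thinned to 60% of its islands gave an overlap of 60.0%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.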

Results

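The distribution of mSin3A, the scaffold protein of a histone deacetylase co-repressor complex, was mapped by ChIP-seq in mature splenic CD8 T cells with high surface T cell receptor. Cells came from WT mice or from mice in which Tcf1 and Lef1, related HMG-box transcription factors of the T cell lineage, had been deleted by Cre recombinase driven from Cd4 sequences. The question was how loss of both factors alters where mSin3A is found. Each genotype was profiled once in condition 1 and once in condition 2. The WT lists held 13397 islands with 1857866 reads in condition 1 and 11151 islands with 1792952 reads in condition 2. The deficient lists held 15954 islands with 1901826 reads and 13556 islands with 1917097 reads, respectively.

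More and narrower mSin3A islands were listed for deficient than for WT cells in both conditions. The number was 1.19 times the WT number in condition 1 and 1.22 times in condition 2. Median island width was 3199 bp in deficient against 3599 bp in WT cells in condition 1, and 3799 bp against 4199 bp in condition 2. Covered length changed less, from 64.8 to 65.5 Mb in condition 1 and from 61.1 to 65.5 Mb in condition 2, which are ratios of 1.01 and 1.07. Mean read density over covered bases was nearly level, at 28.7 and 29.3 reads per kb in the WT libraries and 29.0 and 29.3 reads per kb in the deficient libraries. The change between conditions was of a similar size: the condition 2 list was 0.832 times as long as the condition 1 list in WT and 0.850 times in deficient cells. With 1 library in each group, these differences have no replicate check and no test was made.

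mSin3A islands of the 2 genotypes coincided far more often than under random placement, but about as incompletely as the islands of the WT libraries did with each other. In condition 1, 62.2% of WT islands (95% interval 61.4 to 63.0) overlapped an island of deficient cells, and 54.3% of deficient islands (53.6 to 55.1) overlapped a WT island. In condition 2 these shares were 66.2% (65.3 to 67.0) and 56.3% (55.5 to 57.1). Random placement gave between 4.83% and 5.85% on average, and no placement reached the observed share (one-sided permutation p = 0.001, the smallest that 1000 placements can give, for every overlap tested and so also after Benjamini-Hochberg adjustment). Placement was uniform along the chromosomes and did not allow for places where islands are rarely called in any library, so passing it was a low bar. Between conditions, 57.4% of the islands of WT condition 1 were met in WT condition 2 and 66.8% in the other direction. The deficient libraries resembled each other more, with 69.1% and 78.5%.

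**Figure D1:**
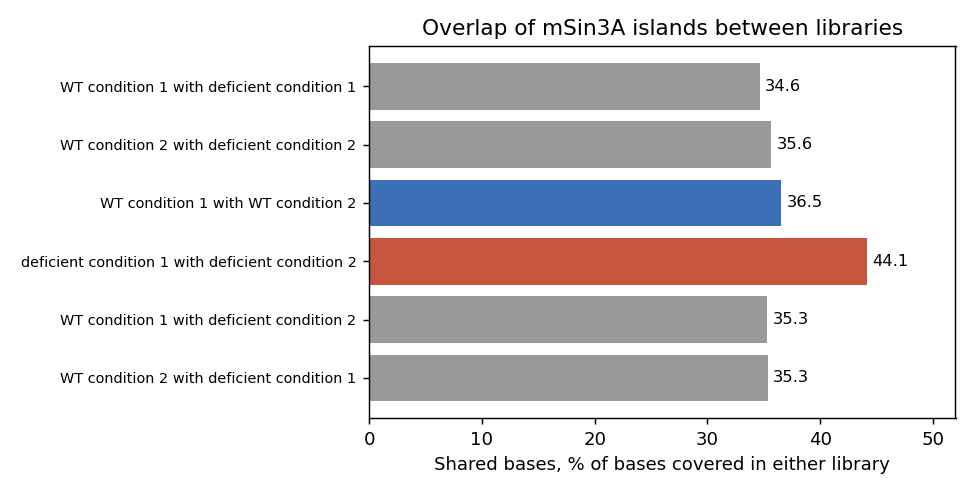
Bases shared by each pair of libraries, as a percentage of the bases covered in either (horizontal axis, from 0), with 1 bar per pair and no error bars because each group is 1 library. The deficient pair shares 44.1% of its bases, the WT pair 36.5%, and the pairs of different genotype 34.6% to 35.6%.

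By bases, the 2 deficient libraries shared 44.1%, the 2 WT libraries 36.5%, and pairs of different genotype 34.6% in condition 1, 35.6% in condition 2 and 35.3% for both pairs that crossed conditions. The WT pair thus lay only 0.876 percentage points above the closest pair of different genotype. With every list held to the 11151 islands richest in reads, WT islands overlapped the other WT list in 65.4% and 64.1%, and the overlaps between genotypes ran from 62.7% to 67.8%, so that by this measure WT libraries were not more alike than libraries of different genotype. The deficient pair stayed higher, at 81.4% and 79.4%.

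Of the 23510 merged regions, 5637 were called in all 4 libraries and 11302 in 1 library alone. In both conditions, 685 regions were called in WT and in neither deficient library, and 2111 regions were called in deficient cells and in neither WT library. These 2796 regions compare with 616 that separated the conditions in the same way, 440 for condition 1 and 176 for condition 2. The crossed split gave 584. For both genotypes together, regions called in both libraries of a genotype and missing in the other were more numerous than either alternative division of the same libraries produced. The WT-only count alone, from 1 pair of libraries, exceeded the 616 regions of the condition split, a sum over 2 pairs, by a small margin. It also exceeded each single pair of different genotype (440, 176, 247 and 337 regions). In the upper 50% of each list by reads, 209 WT-only regions stood against sums of 453 for the condition split and 384 for the crossed split. By single pairs these were 357 and 96, and 176 and 208. There, 751 regions were deficient-only. For the deposited lists the ratio of deficient-only to WT-only regions was 3.08 (exact 95% interval 2.83 to 3.36). With lists of equal length this ratio was 1.75 (1.60 to 1.92), from 1263 and 720 regions.

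**Figure D2:**
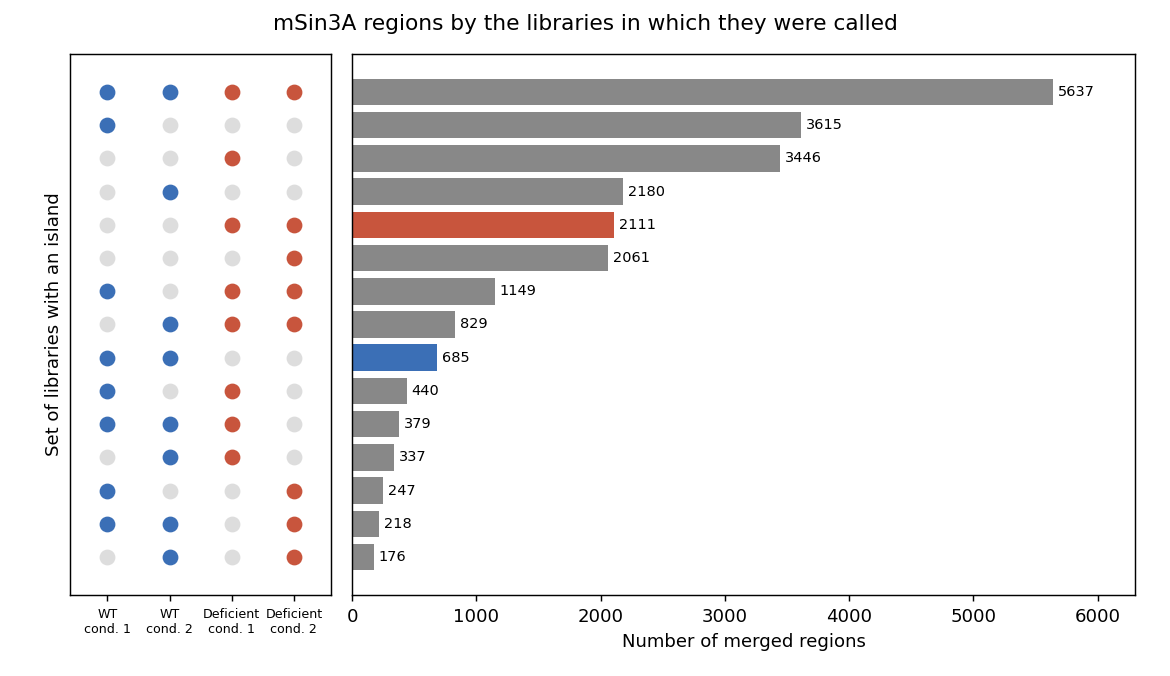
Number of merged mSin3A regions (bars, right) for each set of libraries in which an island was called (coloured dots, left; blue for WT and red for Tcf1/Lef1-deficient). The deficient-only set holds 2111 regions (red bar) and the WT-only set 685 (blue bar), while the sets that join 1 WT and 1 deficient library hold between 176 and 440.

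The libraries differed in how completely they recovered regions seen elsewhere. Of the regions called in the other 3 libraries, WT condition 1 recovered 87.2% (Wilson 95% interval 86.3 to 88.0) and WT condition 2 83.1% (82.2 to 83.9). The deficient libraries recovered 96.3% (95.8 to 96.7) and 93.7% (93.1 to 94.3). This difference moves with the larger number of deficient-only regions. Genotype-specific regions held fewer reads than shared ones: the median was 74 and 79 reads in the WT libraries for WT-only regions and 78 and 87 reads in the deficient libraries for deficient-only regions, against 155 to 174 reads in regions called in all 4. They reached the upper 50% of their list in 20.7% to 35.1% of cases.

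Genotype-specific calls recurred across conditions more often than they switched. There were 3380 regions called in exactly 1 genotype in each condition, and in 2796 of them (82.7%) it was the same genotype (odds ratio 17.4, 95% interval 14.4 to 20.9, two-sided Fisher's exact p = 1.34e-241). Many calls made in 1 genotype within a single condition were not found again in the other condition, however. Of 4765 regions called only in WT in condition 1, 14.4% were again WT-only in condition 2 and 75.9% were called in neither library there. Of 6723 regions called only in deficient cells in condition 1, 31.4% were again deficient-only and 51.3% were called in neither. Of 3581 regions called only in WT in condition 2, 19.1% were again WT-only in condition 1 and 60.9% were called in neither. Of 5568 regions called only in deficient cells in condition 2, 37.9% were again deficient-only, 20.6% were called in both genotypes and 37.0% in neither.

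Among the WT-only regions, the highest read rank belonged to chromosome 10, 7228801 to 7238399, with 3047 and 3168 reads in conditions 1 and 2. The named set also held 3 neighbouring regions of chromosome 4, starting at 119700601, 119721001 and 119783801, with 450 and 513, 372 and 370, and 255 and 328 reads. Chromosome 5, 141110201 to 141129599, held 436 and 465 reads. Chromosome 1 gave 92982401 to 92996399, with 297 and 349 reads, and 85186001 to 85199399, with 239 and 333 reads. The remaining named regions were chromosome 15, 78719201 to 78732199 (282 and 349 reads), chromosome 17, 31456001 to 31471399 (339 and 272 reads), and chromosome 19, 45863801 to 45875799 (228 and 281 reads). Apart from the chromosome 10 region, with 317 and 396 reads per kb, these had 21.9 to 36.1 reads per kb, near the median of 26.5 and 28.2 reads per kb over all WT islands. Merging within 2 kb ended the WT-only call of the chromosome 19 region.

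**Figure D3:**
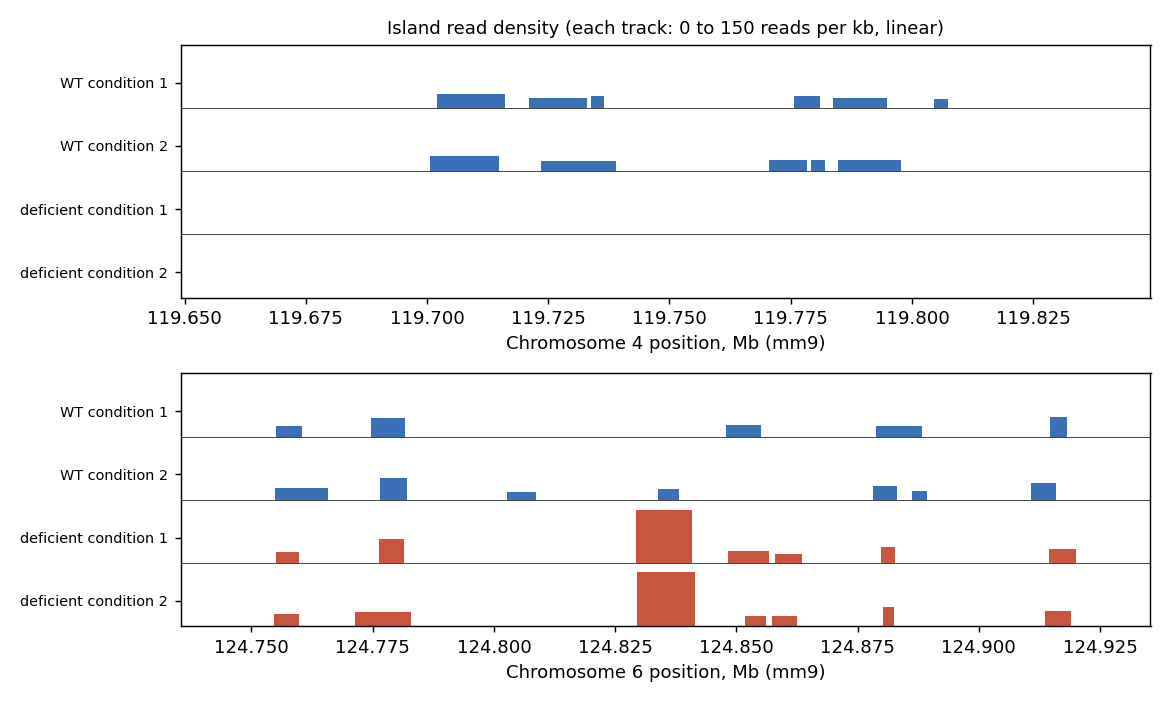
Islands of the 4 libraries (rows; blue for WT, red for deficient) along 2 stretches of mm9, with bar height giving read density on 1 linear scale from 0 in every row. Above, the chromosome 4 stretch with 3 named WT-only regions has no deficient island; below, on chromosome 6, a region chosen after its values were seen (124829401 to 124841399) holds 1441 and 1521 reads in deficient cells and 117 reads in WT condition 2.

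Deficient-only regions were led by chromosome 17, 39979801 to 39985999, which held 9074 and 9080 reads, or 1513 and 1465 reads per kb, the most reads of any island in either deficient list. The input libraries were not analysed here, so the background at this and the other very dense regions is unknown. Chromosome 18, 3002601 to 3013599, held 1242 and 1442 reads, and chromosome 1, 90168001 to 90207399, held 1234 and 2227 reads. Chromosome 5, 15050401 to 15057199, held 420 and 493 reads, and the 1199 bp of chromosome 11, 108872801 to 108873999, held 433 and 464 reads. The others were chromosome 7, 149554001 to 149575799 (455 and 546 reads), chromosome 5, 65064201 to 65080599 (423 and 353 reads), chromosome 4, 88400401 to 88413599 (300 and 341 reads), chromosome 1, 87530801 to 87555199 (253 and 461 reads), and chromosome 5, 121157201 to 121168599 (275 and 296 reads). The last of these lost its deficient-only call when regions within 2 kb were merged. A region not listed in a library has an unknown read number there, so no fold can be given for either set.

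Of the 5 strongest regions called in all 4 libraries, 4 differed little in reads between genotypes. Chromosome 6, 47597801 to 47637199, held 6291 and 6273 reads in WT and 6293 and 6548 in deficient cells. The adjacent 47687001 to 47729799 held 6427 and 6508 against 6328 and 6518 reads. Chromosome 11, 52060401 to 52130599, held 2252 and 2504 against 2372 and 2441 reads, and chromosome X, 92118601 to 92178599, held 1793 and 2021 against 2003 and 2247 reads. In contrast, chromosome X, 166409601 to 166447199, held 3865 and 3835 reads in WT and 7206 and 7524 reads in deficient cells. Its densities were closer, at 174 and 163 reads per kb in WT and 192 and 200.1 reads per kb in deficient cells, so that most of this gap lay in the called length. With the input libraries not analysed, the background at these 5 regions is unknown, and their read numbers may not reflect mSin3A alone.

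Across the 5637 regions called in all 4 libraries, read numbers varied between genotypes about as much as between conditions. The standard deviation of the log2 ratio of deficient to WT was 0.50 in condition 1 and 0.52 in condition 2, and that of condition 2 to condition 1 was 0.51 in WT and 0.44 in deficient cells. At least 2-fold more reads in deficient cells in both conditions were found in 18 regions, and at least 2-fold fewer in 23 regions. Scaling by total island reads in place of the median gave 13 and 38 regions. Another 24 regions passed 2-fold in opposite directions. The log2 ratios of the conditions were weakly correlated across regions, which are not independent replicates (Pearson r = 0.11, Spearman rho = 0.11; permuting one ratio over regions gave r between -0.03 and 0.03 in 95% of draws).

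Within each condition, the read ratios followed called length. Across regions, the log2 ratio of reads correlated with the log2 ratio of called length at r = 0.87 in condition 1 and r = 0.89 in condition 2. The length ratios themselves did not correlate between conditions beyond the permuted range (r = 0.022; permuted -0.026 to 0.026). Per kb of called length, Pearson's r between the conditions lay inside the permuted range (r = 0.015, permuted -0.026 to 0.027). Spearman's rho lay slightly above it (rho = 0.032, permuted -0.025 to 0.025). By this measure 3 regions were at least 2-fold higher and 2 at least 2-fold lower in deficient cells in both conditions, while 4 passed 2-fold in opposite directions. The denser ones were chromosome 15, 57737001 to 57747199, chromosome 3, 58377601 to 58381799, and chromosome 8, 4777601 to 4780399, all with fewer reads but shorter called lengths in deficient cells. The less dense ones were the chromosome 1 region described next and chromosome 9, 20410001 to 20416199, where deficient cells had more reads, 125 and 156 against 82 and 81. In the 1233 regions whose called length agreed within 1.5-fold in all 4 libraries, r was 0.31 (permuted -0.055 to 0.058). Spearman's rho was 0.25 (permuted -0.058 to 0.056). In these regions the standard deviation of the log2 ratio was 0.25 and 0.24 between genotypes, against 0.205 and 0.195 between conditions. The chromosome 1 region alone differed by 2-fold in both conditions. Because called length moves with reads, this selection itself leaves out most regions with large ratios, so its low count does not show that differences are absent.

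**Figure D4:**
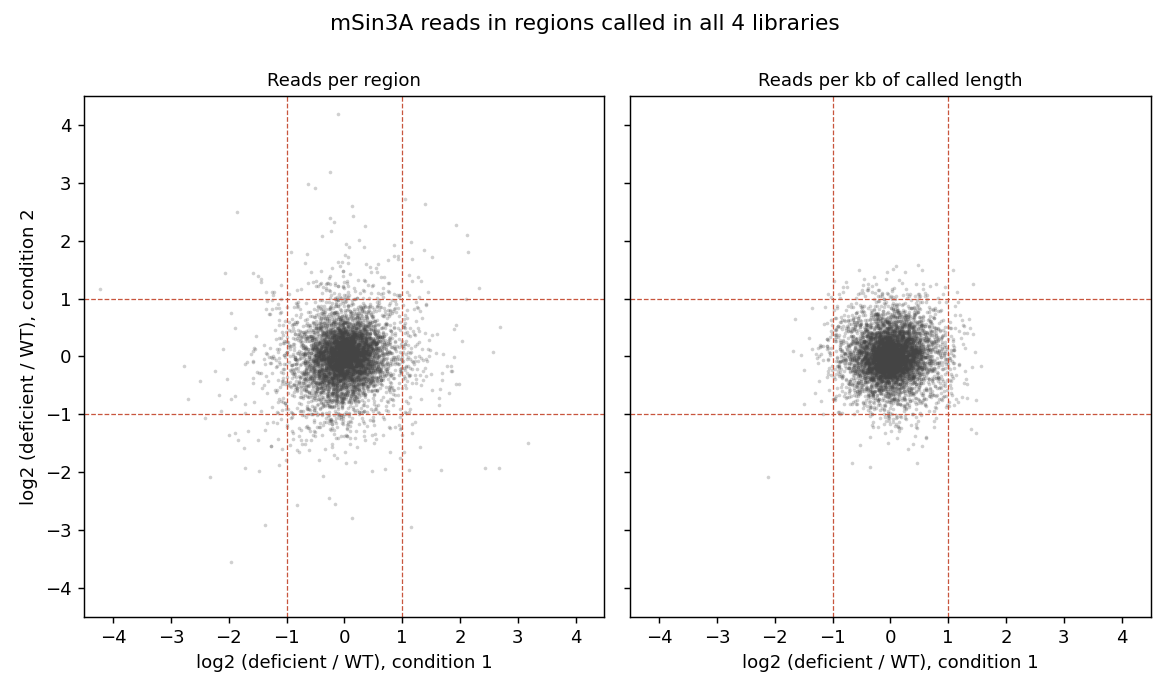
Log2 ratio of deficient to WT mSin3A reads in condition 1 (horizontal) and condition 2 (vertical), 1 point for each of 5637 regions called in all 4 libraries, centred on the median; left, reads per region, and right, reads per kb of called length. Dashed lines mark 2-fold; in the right panel the point that stands apart at the lower left is the chromosome 1 region starting at 167765201.

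The region with the clearest difference in both measures lay on chromosome 1, 167765201 to 167795999. It held 2709 and 2720 reads in WT against 518 and 604 in deficient cells, which was 5.01-fold (95% interval 4.56 to 5.52) and 4.24-fold (3.89 to 4.64) higher in WT after centring. Its density was 98.2 and 107 reads per kb in WT and 22.7 and 25.2 reads per kb in deficient cells. Because the input libraries were not analysed, an effect of the input or copy number here cannot be told apart from a difference in mSin3A. The next regions with fewer reads in deficient cells differed in called length far more than in density. On chromosome 8, 114092001 to 114124199 held 471 and 626 reads in WT against 116 and 50, over 21797 and 30198 bp against 4199 and 2599 bp. Chromosome 7, 16580001 to 16599199, held 376 and 337 reads against 110 and 83. Chromosome 2, 28949801 to 28959199, held 219 and 172 against 63 and 54 reads, and chromosome 4, 133274401 to 133290999, held 208 and 334 against 72 and 80 reads.

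In the opposite direction, chromosome X, 72973801 to 73007799, held 99 and 176 reads in WT against 415 and 711 reads in deficient cells, a ratio of 4.37 (3.51 to 5.50) in condition 1 and 4.29 (3.63 to 5.08) in condition 2. Its called length grew from 5399 to 20598 bp and from 8399 to 32198 bp. Chromosome 1 contributed 107886001 to 107890799, with 51 and 45 against 186 and 204 reads, 90517201 to 90527599, with 38 and 61 against 160 and 202 reads, and 54956001 to 54970799, with 41 and 79 against 113 and 246 reads. Chromosome 14, 54780601 to 54797199, held 133 and 57 against 334 and 333 reads. Per kb, none of these 5 regions was 2-fold higher in deficient cells in both conditions, and the chromosome 1 region starting at 54956001 was lower.

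None of 20 chromosomes passed an adjusted p of 0.05 in either condition (Fisher's exact test), and 2 in condition 1 and 1 in condition 2 passed without adjustment. Chromosome 4 held 7.0% of WT and 6.24% of deficient islands in condition 1 (adjusted p = 0.175, Fisher's exact test) and 6.99% and 6.25% in condition 2 (adjusted p = 0.38, Fisher's exact test). Chromosome X held 1.46% of WT and 1.81% of deficient islands in condition 1 (adjusted p = 0.212, Fisher's exact test) and 1.49% and 1.62% in condition 2 (adjusted p = 0.953, Fisher's exact test). By covered bases, which were not tested, its share was 0.940% in WT and 1.32% in deficient cells in condition 1 and 0.928% and 1.19% in condition 2, which moved the log2 ratio of the shares from 0.31 to 0.49 and from 0.12 to 0.36. No list held an island on chromosome Y.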

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

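The tests of list length, island joining and read rank were set before their results were seen; those of independent misses and of read density were chosen afterwards. In 247 regions the call was WT-only in condition 1 and deficient-only in condition 2, and in 337 regions it was the reverse, so that the calls of the genotypes went in opposite directions in the 2 conditions. The difference was not tested for any single region. As a set, these are the 584 regions set against 2796 that kept their genotype in the recurrence test (odds ratio 17.4), so switched calls were the fewer.

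The larger number of deficient-only regions is the first pattern. Unequal list length did not account for all of it, since the ratio to WT-only regions was 1.75 with equal lists, although it was 3.08 before. Splitting of islands over gaps of up to 2 kb did not account for it either (3.03 after merging within 2 kb). Merging does not make island widths equal, so a part of narrower islands in the ratio was not tested. Among regions in the upper 50% of both lists of their genotype and absent from the other, the ratio was 5.65. That cut was made within each list, at medians of 94 and 112 reads in deficient lists against 106 and 127 reads in WT lists. Because deficient regions passed a lower bar, this ratio cannot decide whether misses near the calling limit of the WT libraries contributed. Independent misses at matched read rank would leave 341 WT-only regions (Poisson 95% range 306 to 378) and 1386 deficient-only regions (1314 to 1460). The observed numbers were 2.01 and 1.52 times these. The excess of deficient-only over WT-only regions was thus already present in the expected numbers, and in proportion larger there. Lower recovery by the WT libraries could therefore give this excess. The expected numbers come from call rates in the other genotype, however, which a true absence lowers too. A lower sensitivity of the WT libraries, misses that both libraries of a genotype share because they may have been called against the same input, and the genotype itself were not separated by any of these values and stay open.

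The second pattern is the very dense regions called in 1 genotype, among the 8433 regions called either in all 4 libraries or in both libraries of 1 genotype alone. Density here is the highest over the libraries that called the region. For shared regions it is taken over 4 libraries and for the others over 2, which moves shared regions towards higher classes and raises the 1-genotype share in the lowest class. The share called in a single genotype was 98.4% below 20 reads per kb, 11.5% at 40 to 100 and 36.8% above 100 reads per kb (14 of 38 regions against 375 of 3267, two-sided Fisher's exact p = 5.22e-05). In the upper 50% of every list that called them it was 25% above 100 reads per kb (7 of 28) against 3.71% at 40 to 100 (64 of 1727, two-sided Fisher's exact p = 7.91e-05, adjusted p = 0.000158 over the 2 rank classes), which argues against misses near the calling limit for these 7 regions. The other 7 (70% of 10 regions) held as few as 16 reads, and such misses stay open for them. An effect of the input, copy number or repeats on the 14 regions, of which 10 are deficient-only and 4 WT-only, cannot be told apart from a difference in mSin3A, because the input libraries were not analysed here.

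Leaving out the 62 regions of any call pattern above 100 reads per kb left 681 WT-only and 2101 deficient-only regions.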

How the results depend on the processing

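Each group is 1 library, so no replicate could be left out. Genotypes were compared within each condition, and a model with genotype and condition as terms was not run, because the reads of a region are counted over a different called length in each library. All overlaps stayed above random placement under every alternative run. They ranged between genotypes from 34.7% to 43.9% with a reciprocal overlap of 50% and from 65.8% to 78.8% for the upper 50% of each list, and between conditions from 36.9% to 53.6% and from 67.5% to 85.0%. Island numbers and covered lengths stayed within 1.5-fold, and the odds ratio for recurrence stayed above 1 (4.29 to 38.9). Counts of genotype-specific regions moved with the threshold: WT-only and deficient-only regions numbered 209 and 751 for the upper 50%, and 85 and 480 when the upper 50% of the own lists was set against the full lists of the other genotype. WT-only regions were then fewer than the condition split, which sums 2 pairs of libraries (453 and 89 regions, respectively). By single pairs, the 209 lay below the 357 for condition 1 but above the 96 for condition 2 and the crossed 176 and 208. The 85 exceeded every such pair (73, 16, 30 and 35). With lists of equal length, which compares fewer islands, there were 1263 deficient-only regions in place of 2111, and WT-only regions numbered 720. Of the 20 named genotype-specific regions, 18 kept that call when merged within 2 kb. Shortening the lists by reads could not end such a call, since these regions were chosen by read rank. Regions with 2-fold more or fewer reads in deficient cells in both conditions depended on the measure. Scaling by total island reads gave 13 with more and 38 with fewer, against 18 and 23. Regions of similar called length, a selection that itself leaves out most large ratios, gave 0 with more and 1 with fewer. Reads per kb gave 3 with more and 2 with fewer, and 4 in opposite directions. Per kb, the mean log2 ratio over the conditions reversed for chromosome 1 from 54956001 (-0.57, from 1.62), chromosome 8 from 114092001 (0.12, from -2.76) and chromosome 4 from 133274401 (0.44, from -1.72), where called length differed between genotypes. The gene list comparisons and their 3 alternatives were not run, for want of an mm9 annotation. Total depth is unknown, which limits any statement on regions not called.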

Other observations

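Of the tests in this part, those on regions called in 3 libraries were chosen after their values were seen, and those on neighbouring regions before, except that the Wilson intervals of their shares were added afterwards.

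One region stood out among those called in 3 libraries. Chromosome 6, 124829401 to 124841399, held 1441 and 1521 reads in the deficient libraries, 117 reads in WT condition 2, and no island in WT condition 1. In condition 2 this was 13.0-fold more reads in deficient cells (exact 95% interval 10.8 to 15.8, counting error only), with 129 against 26.6 reads per kb, a 4.85-fold difference in density, both without centring. The reads were summed over 11799 bp of called length in deficient cells and 4399 bp in WT, which is part of the fold in reads and is not covered by its interval. The limits of 4-fold in reads and 2-fold in density used next were set with this region's values in view, so that its passing them is no independent evidence. Of 1978 regions called in both deficient libraries and in 1 WT library, 7 had at least 4-fold more reads than in that WT library after centring the reads as in the shared regions, 1 of which, this region, was also at least 2-fold denser, while 18 had at least 4-fold fewer. Of 597 regions called in both WT libraries and in 1 deficient library, 14 had at least 4-fold more reads in WT, 0 were also 2-fold denser, and 2 had at least 4-fold fewer. The adjacent regions of chromosome 6 also varied in where they were called: 124802801 to 124808599 in WT condition 2 alone, and 124847801 to 124856799 in 3 libraries, with 191 reads in WT condition 1 and 253 and 108 reads in deficient cells. Which gene lies there was not determined here. Because the input libraries were not analysed, an effect of the input, copy number or repeats at this region cannot be told apart from a difference in mSin3A.

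The island with the most reads of all lay on chromosome 11, 3018201 to 3103999, in WT condition 1, with 23922 reads or 1.29% of that library's island reads. The region held 113 and 126 reads in the deficient libraries and no island in WT condition 2, so the difference was not shared by the WT libraries. Because the input libraries were not analysed, an effect of the input, copy number or repeats on this island cannot be told apart from mSin3A.

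The chromosome 4 stretch between 119700601 and 119797799, which holds 3 of the 10 named WT-only regions, had no island in either deficient library. The 1 Mb window around it held 6 WT-only and 1 deficient-only region of 22. No 1 Mb window held more WT-only regions, and 1 other, on chromosome 4 from 134 to 135 Mb, held as many, with 2 deficient-only of 46. The most deficient-only regions in 1 Mb numbered 7, reached for example on chromosome 11 from 69 to 70 Mb, with 0 WT-only regions there.

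A hypothesis was that genotype-specific regions may cluster with others of the same genotype. For neighbours under 20 kb apart, 69.9% of 236 pairs had the same genotype, against 63.0% under permuted labels (95% range 57.2 to 69.1; one-sided permutation p = 0.0146, 0.0584 after Benjamini-Hochberg adjustment over 4 distances), so that the excess did not pass the adjusted threshold. At 20 to 100 kb the share was 63.9% (permuted range 58.9 to 66.9), at 100 kb to 1 Mb it was 63.2% (60.7 to 65.3), and at 1 to 10 Mb it was 65.9% (59.3 to 66.7; one-sided permutation p = 0.0738, adjusted p = 0.148). These shares lay inside their permuted ranges, but their Wilson 95% intervals (59.7 to 67.9, 60.6 to 65.7 and 62.0 to 69.5) reached above them. Under the rule set beforehand, the share at 100 kb to 1 Mb counted against megabase segments of copy number or strain origin. By the same rule, the share at 20 to 100 kb went with pieces of one broad domain. The intervals added afterwards allow a small excess at these distances, so neither explanation is taken as settled here.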
